A study of Homo sapiens with 21 samples.

How the data were processed

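RNA was sequenced from ARPE19 cells, a human cell line derived from the retinal pigment epithelium, kept in serum at day 0 or without serum for 1, 3, 4, 5, 6 or 9 days, with 3 biological replicates per day and 21 libraries in all. Per the labels, polyadenylated RNA was sequenced as paired-end reads from indexed libraries. The deposited table holds raw counts per gene symbol, with no normalization, for 24442 symbols. Novoalign 3.02.00, HTSeq 0.61, DESeq 1.12.1, R 3.0.1 and the genome build hg19 are named per the submitters' processing notes. The gene annotation used for counting, the strand setting and the handling of reads with several best matches are not given in the sources used here. Every library was used, and no columns or libraries were merged.

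Library totals ran from 32201189 to 48501353 counts. After scaling, 1 count corresponded to between 0.0206 and 0.038 on the counts-per-million scale (CPM), and a gene with no count in a library was below 3 counts, or 0.0618 to 0.114 CPM. These limits cover counting error only. Genes were kept for testing with edgeR's filterByExpr (minimum count 10, day as group), which left 15000 genes holding 99.98% of all counts; 3943 symbols had no count in any library. Counts were scaled by trimmed mean of M-values (TMM) factors, and log2 CPM values for plots and principal components used a prior count of 2.

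The tests were fixed before the data were examined. Genes were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, in a single fit of all 21 libraries with the day as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15000 genes. By chance alone, 750 of them would be expected at an unadjusted p under 0.05, if p-values were evenly spread. Each day without serum was compared with day 0, neighbouring days were compared with each other, day 9 was compared with day 1, and all days were tested together. Errors given with log2 fold changes are standard errors derived from the F statistic, and errors given with CPM are SDs of 3 libraries. The common biological coefficient of variation was 0.359.

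Of 32 gene lists fixed before the data were examined, 31 had at least 5 tested members and were tested at days 1 and 9 with camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists). Camera with an estimated correlation and fry were run beside it. The same camera test at days 3, 4, 5 and 6 was added after the data were seen. For each list, members were counted over all genes and after p-values were adjusted over the list alone.

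The named genes were chosen by a rule. For day 1 against day 0, day 9 against day 0 and day 9 against day 1, it took the 5 raised and 5 lowered genes with the largest change among called genes with a mean log2 CPM of at least 1 and no overlap between the days, together with the 3 members with the smallest p of each called list. For the other comparisons it took the 2 raised and 2 lowered genes under the same conditions. It always took 12 genes of the cell cycle, sterol metabolism and the pigment epithelium. Genes named outside the rule are marked as chosen after their values were seen. Gene symbols were matched to GENCODE on hg19 for position, length and GC content, and 22668 of 24442 symbols (92.7%) matched, 1506 of them by a synonym.

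The replicate numbers were checked as pairs. After the day means were taken out, libraries with the same number correlated with a median of 0.422 over 63 pairs, against -0.2 over 126 pairs with different numbers. A fit with the replicate number as a block is given beside the fit without it, and its coefficient of variation was 0.276. Taking each comparison alone, the numbers were held to pair where all 3 correlations were over 0.1. This failed for day 3 against 0 (correlations of -0.203, -0.0898 and 0.0217), day 4 against 0 (-0.0224, 0.113 and 0.536) and day 3 against 1 (0.418, 0.422 and -0.0634). There the block has no clear basis. The other alternatives were DESeq2 1.42.0, size factors by relative log expression, scaling by library size only, no filter, a mean of at least 1 CPM, a test against a 1.5-fold change (glmTreat), only the 2 days compared, and leaving out each library. The 6 libraries of a comparison can be divided into groups of 3 in 10 ways. The gene count of each comparison and the list counts of days 1 and 9 were repeated on every such split. Because day 0 serves every comparison with it, the overlap of the calls at days 1 and 9 was set against 50 simulated draws with no effect.

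The tests were run on simulated data with the real library sizes and known changes at day 9. These data held no likeness between libraries with the same replicate number and no library that stands apart. edgeR called 5 of 67 genes changed by 2-fold, 47 of 67 changed by 4-fold and 58 of 66 changed by 8-fold, with 7 false calls among 117. With the replicate block it called 5, 46 and 57, with 8 false calls among 116. DESeq2 called 18, 57 and 60, with 35 false calls among 170. Camera called 2 of 2 changed lists and 0 of 29 unchanged lists. The simulated genes varied independently, whereas the real mitosis list at day 9 had an estimated correlation of 0.758. The run therefore does not test camera on lists whose members vary together. Genes of the Y chromosome and XIST were left out of the text and the figures. Some genes chosen by name before the data were examined are not reported here.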

Results

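The series followed gene expression in ARPE19 cells over 9 days without serum. Each of 7 days had 3 biological replicates, 1 library each. No library was kept in serum past day 0, so time without serum cannot be told apart from time in culture. Totals per library ran from 32201189 counts (day_0 replicate 1) to 48501353 (day_5 replicate 2). Between 16839 and 17861 genes had at least 1 count in a library. RPE65, the retinoid isomerase of the native pigment epithelium, had 6 counts over all 21 libraries and was not tested.

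Replicate 3 differed from replicates 1 and 2 at 6 of the 7 days. COL5A1, a fibrillar collagen chain, lay between 101 and 370 CPM in those 6 libraries and between 1.56 and 11.6 CPM in all libraries of replicates 1 and 2. UCA1, a long noncoding RNA, lay between 0.2 and 0.69 CPM against 65.6 to 443 CPM. RLBP1, the retinaldehyde-binding protein of the pigment epithelium, lay between 0.43 and 1.63 CPM against 8.59 to 43.8 CPM. The 690 measured genes of chromosome 11 had a median difference of -0.65 to -0.48 (log2) in the 6 libraries. In day_3 replicate 3 the chromosome 11 median was 0.03, COL5A1 was at 3.94 CPM and UCA1 at 182 CPM. Over all days, 2448 genes differed between replicate 3 and replicates 1 and 2 in an edgeR fit with the day as a second term, chosen after the data were seen. This fit counted day_3 replicate 3 with replicate 3. It took libraries with the same number as independent, although replicate 3 is a single series, so the count overstates the certainty.

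Day_4 replicate 2 also stood apart, with a shift toward short transcripts. Its median difference from day_4 replicate 1 was 1.41 (log2) for the 2886 shortest genes (110 to 1757 bases) and -0.77 for the 2884 longest. GAPDH, a glycolytic enzyme, stood at 15300 CPM against 1690 to 4960 CPM in the other 20 libraries, and HIF1A, the hypoxia-inducible transcription factor, at 28 CPM against 291 to 1000 CPM. Its TMM factor of 0.718 was the lowest of the 21 libraries.

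**Figure D1:**
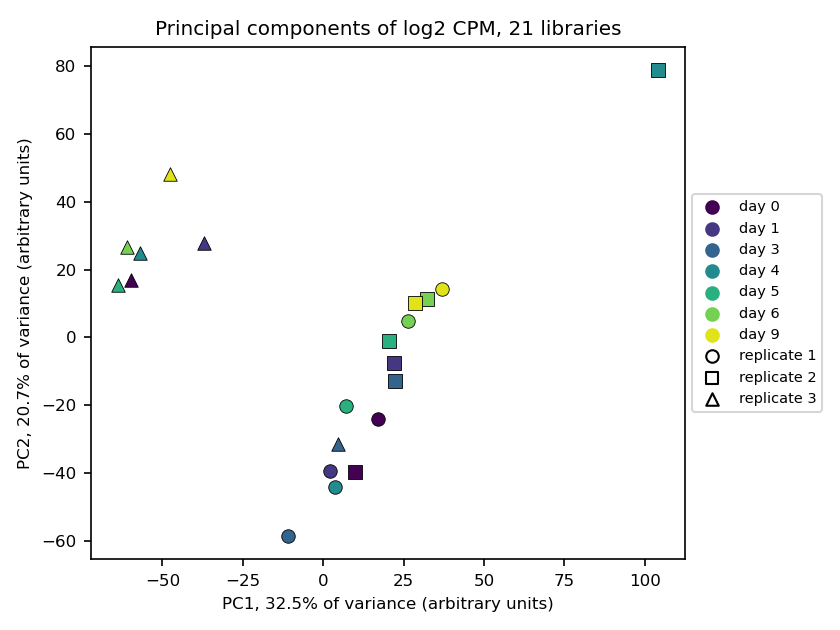
Libraries on principal components 1 and 2 of log2 CPM (arbitrary units, 32.5% and 20.7% of the variance), coloured by day with a marker shape per replicate number. The replicate 3 libraries lie apart from replicates 1 and 2 except at day 3, and day_4 replicate 2 lies away from the other libraries.

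**Figure D2:**
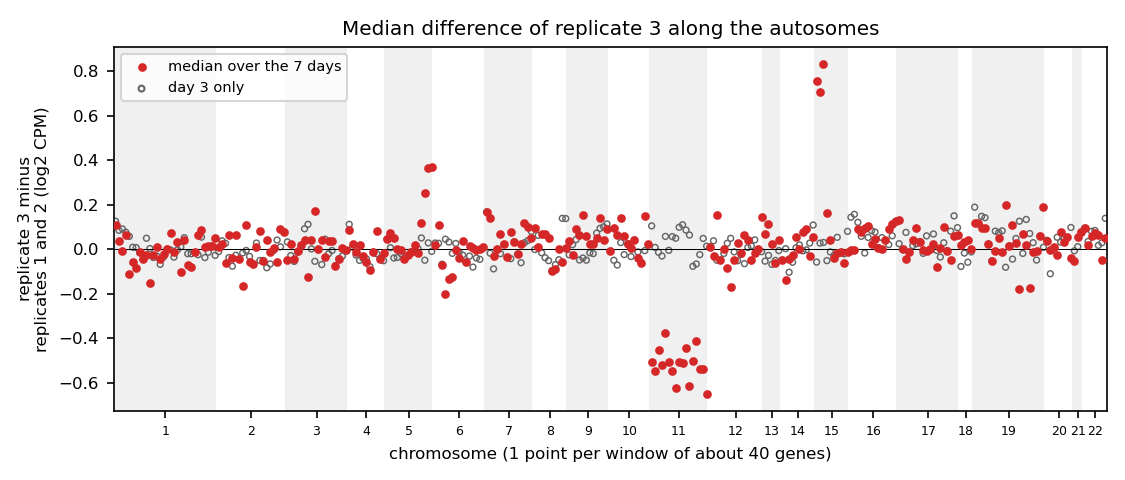
Median difference of replicate 3 from replicates 1 and 2 (log2 CPM) in windows of about 40 neighbouring genes along the autosomes, as the median over the 7 days (filled) and for day 3 alone (open). All 17 windows of chromosome 11 lie below -0.3 over the days, and day 3 lies near 0.

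The comparison of day 1 with day 0 asked how the cells changed within a day of losing serum. Genes for amino acid supply under the transcription factor ATF4 rose as a list, with a positive log2 fold change in 27 of 29 members and a median of 0.70 (camera adjusted p = 2.32e-12, and adjusted p = 0.304 with an estimated correlation). PHGDH, which opens serine synthesis, had a log2 fold change of 1.49 ± 0.29 (SE, n = 3 per day), with 296 ± 26.5 against 106 ± 13.8 CPM. SLC3A2, a subunit of amino acid transporters, had 1.17 ± 0.294 and the tryptophan tRNA ligase WARS 1.01 ± 0.263. Ribosome biogenesis genes rose as a list in 29 of 30 members, with a median of 0.49 (adjusted p = 8.32e-12, and adjusted p = 0.304 with an estimated correlation). RRS1, NOP2 and RRP9, which act in ribosome assembly, had values of 1.44 ± 0.307, 1.00 ± 0.238 and 1.13 ± 0.283. DNA replication genes rose as a list in 37 of 38 members, with a median of 0.55 (adjusted p = 8.16e-10, and adjusted p = 0.666 with an estimated correlation). The helicase subunits MCM7 and MCM3 had values of 0.85 ± 0.209 and 1.00 ± 0.327, and the polymerase clamp PCNA 0.94 ± 0.337. Adjusted over the list alone, 12 amino acid response genes, 13 ribosome biogenesis genes and 1 DNA replication gene passed upward, and over all genes 0 members of any of these lists passed.

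Hypoxia and glycolysis genes fell as a list at day 1, with a positive value in 3 of 28 members and a median of -0.78 (camera adjusted p = 4.35e-07, and adjusted p = 0.666 with an estimated correlation). PDK1, which restrains pyruvate oxidation, had a log2 fold change of -1.55 ± 0.426 (SE, n = 3 per day), NDRG1 -1.59 ± 0.463 and the glucose transporter SLC2A3 -0.97 ± 0.32. Collagen and matrix genes also fell as a list, with 5 of 32 positive and a median of -0.75 (adjusted p = 5.28e-05, and adjusted p = 0.666 with an estimated correlation). The laminin chain LAMC1 had a value of -1.05 ± 0.23 and the collagen cross-linking enzyme LOXL2 -1.44 ± 0.449, while COL3A1, at -1.67 ± 0.546, stayed under 1 CPM at both days. Genes associated with quiescence fell as a list, with 8 of 28 positive and a median of -0.25 (adjusted p = 0.00459, and adjusted p = 0.666 with an estimated correlation). TXNIP, a thioredoxin-binding regulator of glucose uptake, had a value of -2.14 ± 0.517, the repressor BCL6 -1.14 ± 0.307 and PDK4 -1.49 ± 0.423. Adjusted over the list alone, 2 hypoxia genes, 1 matrix gene and 3 quiescence genes passed downward, and 0 passed over all genes. Without day_0 replicate 3 the hypoxia list had an adjusted p of 0.0815, the matrix list of 0.168 and the quiescence list of 0.0702. This fit kept day_1 replicate 3 without a day 0 library of the same number. Of 13 alternatives with the preset correlation, some chosen after the data were seen, 12 called the matrix list. The hypoxia and quiescence lists were each called in 11. The quiescence list was also not called without day_1 replicate 1, nor the hypoxia list with replicates 1 and 2 only, chosen after the data were seen.

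The snoRNA host genes rose as a list at day 1, with 16 of 18 positive and a median of 0.37 (camera adjusted p = 0.0266, and adjusted p = 0.666 with an estimated correlation). DANCR, SNHG15 and SNHG11 had values of 0.79 ± 0.317, 0.77 ± 0.399 and 0.85 ± 0.455 (SE, n = 3 per day). The SRF and YAP targets fell as a list, with 7 of 27 positive and a median of -0.18 (adjusted p = 0.0456, and adjusted p = 0.666 with an estimated correlation). F3, CNN1 and ANKRD1 had values of -0.97 ± 0.288, -3.03 ± 1.03 and -1.40 ± 0.484. CNN1 was low, at 0.229 ± 0.0674 against 1.9 ± 2.29 CPM. No member of these 2 lists passed over all genes or adjusted over the list alone. The SRF and YAP list was not called with the replicate block (adjusted p = 0.0634), nor without day_0 replicate 1, day_0 replicate 3 or day_1 replicate 1. The snoRNA host list was not called without day_0 replicate 2, day_0 replicate 3 or day_1 replicate 1, and its highest adjusted p was 0.347, without day_0 replicate 3. Neither of these 2 lists was called with replicates 1 and 2 only, an alternative chosen after the data were seen. The other 23 lists were not called at day 1, with adjusted p from 0.184 (ERK-responsive genes) to 0.991 (retinoid-responsive genes). Cholesterol synthesis and uptake had an adjusted p of 0.983. Mitosis had 0.212, and its direction turned on single libraries. It was called upward without day_1 replicate 1 (adjusted p = 0.00197, and adjusted p = 0.92 with an estimated correlation). It was called downward without day_1 replicate 2 (adjusted p = 0.00391, and adjusted p = 0.741 with an estimated correlation), without day_1 replicate 3 (adjusted p = 6.06e-08, and adjusted p = 0.52 with an estimated correlation) and with replicates 1 and 2 only (adjusted p = 0.000251, and adjusted p = 0.801 with an estimated correlation).

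Of the genes fixed by name, none was called at day 1. MKI67, a marker of cycling cells, had a log2 fold change of -0.13 ± 0.459 (SE, n = 3 per day), with day_1 replicate 1 at 42.7 CPM and the other day 1 libraries at 188 and 206 CPM. The CDK inhibitor CDKN1A had a value of -0.38 ± 0.274. APOE, which carries lipid out of cells, had 0.06 ± 0.852 and the complement component C3 0.00 ± 0.39. The matrix proteins EFEMP1 and TIMP3 had -0.92 ± 0.526 and -0.57 ± 0.277, the secreted factor SERPINF1 -0.07 ± 0.381 and the angiogenic factor VEGFA -0.03 ± 0.414. Among single genes at day 1, edgeR called 0, with 2028 at an unadjusted p under 0.05, and DESeq2 called 280 (116 up, 164 down). With the replicate block 15 genes passed, 4 up and 11 down. Among these, chosen after their values were seen, the basement membrane protein NID2 had -2.03 ± 0.338 (adjusted p = 0.0377) and the RNA export factor NXF1 0.95 ± 0.169 (adjusted p = 0.0442). Without day_0 replicate 3 the count without the block was 419, without day_4 replicate 2 it was 69 and without day_4 replicate 3 it was 3. The block fit without both day_3 replicate 3 and day_4 replicate 2, chosen after the data were seen, called 1376.

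At day 3 against day 0, PHGDH (hg19 chromosome 1, 120191034 to 120286841) rose by a log2 fold change of 1.79 ± 0.293 (SE, n = 3 per day; edgeR adjusted p = 0.0379; 365 ± 82.5 against 106 ± 13.8 CPM). NID2 (chromosome 14, 52471527 to 52535777) fell, with -2.50 ± 0.353 (adjusted p = 0.0195; 26.5 ± 2.87 against 150 ± 50.5 CPM). GPCPD1, a glycerophosphodiesterase (chromosome 20, 5525085 to 5591652), fell, with -1.95 ± 0.317 (adjusted p = 0.0379). The retinol dehydrogenase RDH10, named after its values were seen, fell, with -1.79 ± 0.295 (adjusted p = 0.0379). These 4 genes were the calls, with 2154 genes at an unadjusted p under 0.05. The replicate block gave 367, although the replicate numbers of days 0 and 3 did not pair, and DESeq2 529 (201 up, 328 down). The count was 0 without any 1 of day_0 replicate 1, day_0 replicate 2 and the 3 day 3 libraries, and it was 458 without day_0 replicate 3. Without day_4 replicate 2, day_4 replicate 1 or day_4 replicate 3 it was 214, 47 and 72. Without day_9 replicate 1 it was 7, and without any 1 of the day 1, 5 and 6 libraries or day_9 replicate 2 it was 1.

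The lists at day 3, tested there only after the data were seen, gave 12 calls. The amino acid response rose with a median of 0.92 and 26 of 29 positive (camera adjusted p = 2.96e-17, and adjusted p = 0.123 with an estimated correlation). Of the cholesterol synthesis and uptake genes, 24 of 24 were positive, with a median of 0.93 (adjusted p = 7.2e-06, and adjusted p = 0.388 with an estimated correlation). Against the day 0 mean, the list median was -0.50 in replicate 1, 1.60 in replicate 2 and 1.06 in replicate 3, so the rise was absent from replicate 1. Ribosome biogenesis (median 0.51, adjusted p = 5.5e-11, and adjusted p = 0.156 with an estimated correlation), DNA replication (median 0.59, adjusted p = 1.82e-08, and adjusted p = 0.387 with an estimated correlation) and fatty acid synthesis (median 0.40, adjusted p = 0.00067, and adjusted p = 0.156 with an estimated correlation) also rose. Collagen and matrix genes fell, with 3 of 32 positive, a median of -1.13 and 13 members down when adjusted over the list alone (adjusted p = 5.5e-11, and adjusted p = 0.156 with an estimated correlation). The other lists that fell were genes of quiescence (median -0.45, adjusted p = 1.14e-06, and adjusted p = 0.123 with an estimated correlation) and hypoxia (-0.60, adjusted p = 6.17e-06, and adjusted p = 0.36 with an estimated correlation). Matrix proteases (-0.74, adjusted p = 0.000374, and adjusted p = 0.156 with an estimated correlation) and lysosome genes (-0.34, adjusted p = 0.000489, and adjusted p = 0.357 with an estimated correlation) fell too. Complement (-0.64, adjusted p = 0.00255, and adjusted p = 0.225 with an estimated correlation) and genes at macular degeneration loci (-0.35, adjusted p = 0.0358, and adjusted p = 0.34 with an estimated correlation) fell as well, the latter with 0.0507 without day_4 replicate 2. With replicates 1 and 2 only, run after the data were seen, the matrix list had a median of -1.03 (adjusted p = 2.98e-07, and adjusted p = 0.201 with an estimated correlation), so its decrease did not rest on replicate 3. Fatty acid synthesis (0.0806) and the macular degeneration loci (0.0784) were not called there. The hypoxia list fell less there, with a median of -0.335 (camera adjusted p = 0.0405) and 11 of 28 positive, against 2 of 28 with all libraries. Without day_3 replicate 3 alone all 12 lists were called. That fit kept day_0 replicate 3, which held the replicate 3 difference, so it does not test whether the lists rest on that library. COL5A1, high in the other replicate 3 libraries, had a value of -5.44 ± 2.34 (adjusted p = 0.297), and -2.44 ± 0.832 with the replicate block. The median of chromosome 11 genes was 0.167 at day 3, against 0.00848 for the other autosomes.

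At day 4 against day 0, NID2 fell by 3.09 on the log2 scale, with an SE of 0.362 (n = 3 per day; edgeR adjusted p = 0.00145; 17.7 ± 9.31 against 150 ± 50.5 CPM). CYP24A1, the enzyme that degrades vitamin D (chromosome 20, 52769985 to 52790525), fell, with -2.37 ± 0.401 (adjusted p = 0.0413). The metalloproteinase ADAM19, GPCPD1, LAMC1 and the chromatin regulator JARID2, named after their values were seen, also fell, with -1.97 ± 0.33, -1.91 ± 0.317, -1.35 ± 0.231 and -1.16 ± 0.2. These 6 genes were the calls, with 3422 at an unadjusted p under 0.05, 432 with the replicate block and 1350 by DESeq2 (939 up, 411 down). The replicate numbers of days 0 and 4 did not all pair, so the block has no clear basis in this comparison. NID2 was called with every scaling and filter, by DESeq2, with the replicate block and without any 1 library of days 0 and 4. It was not called in a fit of days 0 and 4 alone, which called 0 genes. The count of 6 fell to 1 without any 1 of day_0 replicate 1, day_0 replicate 2 and day_4 replicate 2. The count was 681 without day_0 replicate 3, 1241 without day_4 replicate 1 and 2223 without day_4 replicate 3. Without day_1 replicate 1 it was 2, and without any 1 of the other day 1 libraries, the day 3, 5 and 6 libraries or day_9 replicate 2 it was 1.

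Of the lists at day 4, tested after the data were seen, 11 were called. Cholesterol synthesis and uptake rose with a median of 1.69 and 18 members up when adjusted over the list alone (camera adjusted p = 1.01e-09, and adjusted p = 0.525 with an estimated correlation), and its median was 0.96 without day_4 replicate 2. The rise was absent from replicate 1, whose list median was -0.16 against the day 0 mean, beside 2.53 and 1.67 in replicates 2 and 3. The amino acid response (median 0.61, adjusted p = 1.1e-05, and adjusted p = 0.525 with an estimated correlation) and ribosome biogenesis (0.44, adjusted p = 0.000183, and adjusted p = 0.525 with an estimated correlation) rose. Fatty acid synthesis (0.57, adjusted p = 0.00419, and adjusted p = 0.369 with an estimated correlation) and DNA replication (0.46, adjusted p = 0.00843, and adjusted p = 0.72 with an estimated correlation) rose as well. Collagens and matrix (median -0.89, adjusted p = 1.27e-08, and adjusted p = 0.36 with an estimated correlation) and quiescence genes (-0.32, adjusted p = 0.000456, and adjusted p = 0.36 with an estimated correlation) fell, as did glucocorticoid-responsive genes (-0.46, adjusted p = 0.00464, and adjusted p = 0.36 with an estimated correlation) and matrix proteases (-0.26, adjusted p = 0.0262, and adjusted p = 0.525 with an estimated correlation). Oxidative phosphorylation had a median of 0.89 (adjusted p = 1.1e-05, and adjusted p = 0.72 with an estimated correlation) and snoRNA hosts of 0.90 (adjusted p = 0.00828, and adjusted p = 0.72 with an estimated correlation). Without day_4 replicate 2, the library rich in short transcripts, these 2 medians were 0.00 and -0.10, with adjusted p of 0.739 and 0.959. Of the lists not called with all libraries, 4 were called downward without it, for a total of 13. They were lysosome genes (adjusted p = 0.000274 against 0.308, and adjusted p = 0.29 with an estimated correlation) and hypoxia (0.0013 against 0.0759, and adjusted p = 0.644 with an estimated correlation). The others were retinoid-responsive genes (0.00881 against 0.47, and adjusted p = 0.29 with an estimated correlation) and pigment epithelium markers (0.0312 against 0.233, and adjusted p = 0.29 with an estimated correlation). The chromosome 11 median at day 4 was 0.163, against 0.042 for the other autosomes.

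At day 5 against day 0, ADM, the vasodilator peptide adrenomedullin (chromosome 11, 10326620 to 10328944), fell by 1.57 on the log2 scale, with an SE of 0.222 (n = 3 per day; edgeR adjusted p = 0.0208; 29.2 ± 5.12 against 86.4 ± 12.1 CPM). It was the single call, with 921 genes at an unadjusted p under 0.05, 9 called with the replicate block (4 up, 5 down) and 86 by DESeq2. The count was 0 without day_0 replicate 1 or any 1 of the day 5 libraries, 50 without day_0 replicate 3, and 4 and 2 without day_4 replicates 1 and 3. Cholesterol synthesis and uptake rose as a list, tested there after the data were seen, with 24 of 24 positive, a median of 1.89 and 21 members up when adjusted over the list alone (camera adjusted p = 2.94e-44, and adjusted p = 0.0277 with an estimated correlation). Fatty acid synthesis and desaturation rose too, with a median of 0.85 and 9 members up when adjusted over the list alone (adjusted p = 1.84e-19, and adjusted p = 0.00081 with an estimated correlation). Among their members, chosen after their values were seen and not called over all genes, the desaturase SCD had a value of 3.24 ± 0.663 (adjusted p = 0.147; 1560 ± 519 against 165 ± 16.7 CPM) and the sterol demethylase CYP51A1 2.07 ± 0.376.

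The 8 other lists called at day 5 went both ways. Mitosis fell with 0 of 35 positive and a median of -0.46 (camera adjusted p = 7.84e-05, and adjusted p = 0.696 with an estimated correlation). NRF2 targets (median -0.43, adjusted p = 0.000407, and adjusted p = 0.463 with an estimated correlation), glucocorticoid-responsive genes (-0.49, adjusted p = 0.00245, and adjusted p = 0.25 with an estimated correlation) and metallothioneins (-1.30, adjusted p = 0.00245, and adjusted p = 0.463 with an estimated correlation) fell. Collagens and matrix (-0.28, adjusted p = 0.00471, and adjusted p = 0.622 with an estimated correlation) and hypoxia (-0.16, adjusted p = 0.0122, and adjusted p = 0.737 with an estimated correlation) fell. The amino acid response (0.22, adjusted p = 0.00442, and adjusted p = 0.643 with an estimated correlation) and interferon-stimulated genes (0.16, adjusted p = 0.0173, and adjusted p = 0.622 with an estimated correlation) rose. The snoRNA hosts were called downward without day_4 replicate 2 (adjusted p = 0.0281 against 0.0502, and adjusted p = 0.72 with an estimated correlation).

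At day 6 against day 0, the sterol and fatty acid lists were high again, with medians of 2.09 (21 members up when adjusted over the list alone, camera adjusted p = 3.7e-38, and adjusted p = 0.049 with an estimated correlation) and 0.81 (10 members up, adjusted p = 2.86e-15, and adjusted p = 0.00324 with an estimated correlation). SCD had a log2 fold change of 3.00 ± 0.656 (SE, n = 3 per day), the desaturase FADS2 2.64 ± 0.59 and CYP51A1 2.13 ± 0.377. These were chosen after their values were seen, and none was called. With the replicate block, FADS2 and CYP51A1 both passed (adjusted p = 0.0297). Interferon-stimulated genes rose (median 0.38, adjusted p = 0.00174, and adjusted p = 0.568 with an estimated correlation). NRF2 targets (-0.62, adjusted p = 0.00174, and adjusted p = 0.568 with an estimated correlation), collagens (-0.26, adjusted p = 0.0129, and adjusted p = 0.696 with an estimated correlation), metallothioneins (-1.13, adjusted p = 0.0175, and adjusted p = 0.668 with an estimated correlation) and mitosis (-0.34, adjusted p = 0.0175, and adjusted p = 0.905 with an estimated correlation) fell. DNA replication (-0.29, adjusted p = 0.0246, and adjusted p = 0.905 with an estimated correlation) and glucocorticoid-responsive genes (-0.40, adjusted p = 0.0246, and adjusted p = 0.568 with an estimated correlation) fell, the latter with 0.0576 without day_4 replicate 2. Over all genes edgeR called 0, with 1322 at an unadjusted p under 0.05, against 58 with the replicate block (28 up, 30 down) and 175 by DESeq2. Without day_0 replicate 3 edgeR called 181, without day_4 replicate 2 it called 24, and without day_4 replicates 1 and 3 it called 2 and 1.

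The comparison of day 9 with day 0 asked what differed after the longest time without serum, and 100 genes were called, 42 up and 58 down. AMTN, an enamel and mineralization protein (chromosome 4, 71384286 to 71398460), rose by 5.87 ± 1.04 (SE, n = 3 per day; edgeR adjusted p = 0.0247; 151 ± 127 against 2.57 ± 1.57 CPM). PMEPA1, a membrane protein that restrains TGF-beta signalling (chromosome 20, 56223448 to 56286592), rose by 2.91 ± 0.587 (adjusted p = 0.0385; 398 ± 222 against 52.9 ± 40.2 CPM), and LDLRAD4, a related protein (chromosome 18, 13217497 to 13652754), by 2.56 ± 0.557. The hair keratin KRT81 (chromosome 12, 52679697 to 52685318), whose sequence is close to other hair keratins so that its reads are uncertain, rose by 3.21 ± 0.659, and the lipase LIPH (chromosome 3, 185224050 to 185270376) by 2.09 ± 0.424. CYP24A1 fell, with -3.01 ± 0.412 (adjusted p = 0.0126; 150 ± 78.2 against 1210 ± 341 CPM). RARRES1 (chromosome 3, 158414681 to 158450278) and DHRS3 (chromosome 1, 12627939 to 12678216), both known as retinoic acid response genes, fell, with -3.04 ± 0.48 and -2.85 ± 0.577. The cytokine IL1B (chromosome 2, 113587328 to 113594393) fell, with -3.85 ± 0.804 (0.713 ± 0.258 against 10.3 ± 11.9 CPM, a day 0 SD above the mean). The GTPase regulator ARHGAP20 (chromosome 11, 110447766 to 110583912) fell, with -2.95 ± 0.578 (3.59 ± 1.56 against 27.7 ± 16.2 CPM).

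The count of 100 stood beside 2181 genes at an unadjusted p under 0.05, 555 called with the replicate block (275 up, 280 down) and 643 by DESeq2 (279 up, 364 down). The block fit without both day_3 replicate 3 and day_4 replicate 2, chosen after the data were seen, called 1812. Scaling by library size only gave 43, 24 up and 19 down, so that the share of calls going up was 55.8% against 42%. No gene was called without day_0 replicate 1 or without day_9 replicate 2, and 3 were called without day_0 replicate 2 or without day_9 replicate 1. AMTN, PMEPA1, LDLRAD4, KRT81, LIPH, DHRS3, IL1B and ARHGAP20 were not among these 3. Without day_9 replicate 3 the count was 64, without day_0 replicate 3 it was 428, without day_4 replicate 2 it was 556 and without day_4 replicate 1 it was 163. It was 41, 39 and 23 without day_3 replicates 1, 2 and 3, 32 and 37 without day_5 replicates 1 and 2, and 24, 25 and 38 without day_6 replicates 1, 2 and 3. SULT1E1 and ODAM, called with no count in any day 0 library, were named after their values were seen. SULT1E1, which sulfates oestrogens, had 221 counts at day 9 and was at least 66.8-fold higher. ODAM, a further enamel-associated gene, had 108 counts and was at least 32.6-fold higher, each against a limit of 3 counts over the 3 day 0 libraries.

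Lists of proliferation genes fell at day 9 with the preset correlation of camera, but were not called with an estimated one. All 35 mitosis genes had a negative log2 fold change, with a median of -1.23 (camera adjusted p = 4.5e-20, and adjusted p = 0.299 with an estimated correlation), and 22 passed downward when adjusted over the list alone but 0 over all genes. MKI67 had a value of -1.78 ± 0.474 (SE, n = 3 per day; 46.2 ± 19.7 against 159 ± 44.3 CPM; edgeR adjusted p = 0.0807), and the mitotic kinesins KIF11 and CENPE -1.26 ± 0.374 and -1.36 ± 0.416. DNA replication genes were negative in 38 of 38 members, with a median of -0.79 (adjusted p = 1.61e-12, and adjusted p = 0.396 with an estimated correlation). The replication licensing factor CDT1 (chromosome 16, 88870197 to 88875666) and the origin recognition subunit ORC1 (chromosome 1, 52838501 to 52870095) fell over all genes, with -1.64 ± 0.359 (adjusted p = 0.0469) and -1.62 ± 0.364 (adjusted p = 0.0487), and 7 members passed adjusted over the list alone. RRM2 had -1.79 ± 0.493. CDT1 and ORC1 were not called without any 1 of the day 0 replicates 1 and 2 and the 3 day 9 libraries, nor with scaling by library size only.

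Lists of lipid synthesis genes were high at day 9 with the preset correlation of camera, but were not called with an estimated one. Cholesterol synthesis and uptake was positive in 24 of 24 members, with a median of 1.5 (camera adjusted p = 2.24e-16, and adjusted p = 0.299 with an estimated correlation), and 17 passed upward when adjusted over the list alone, 0 over all genes and 5 over all genes with the replicate block. CYP51A1 had a log2 fold change of 1.62 ± 0.371 (SE, n = 3 per day; edgeR adjusted p = 0.0509, 0.0224 with the replicate block), the sterol oxidase MSMO1 2.25 ± 0.632 (0.0461 with the block) and the desaturase SC5D 1.17 ± 0.29 (0.0327 with the block). Fatty acid synthesis and desaturation rose, with 11 of 13 positive, a median of 0.58 and 5 up when adjusted over the list alone (adjusted p = 0.000199, and adjusted p = 0.299 with an estimated correlation). SCD had a value of 2.51 ± 0.643 (941 ± 140 against 165 ± 16.7 CPM), FADS2 1.97 ± 0.576 and the acyl-CoA ligase ACSL3 0.74 ± 0.192, none of them called over all genes. Over all genes 5 members of this list passed with the replicate block, SCD (adjusted p = 0.0341), FADS2 (0.0295) and ACSL3 (0.0341) among them. Sterol efflux genes, not called with all libraries and no block (adjusted p = 0.0837), were called with the replicate block (adjusted p = 0.035, and adjusted p = 0.382 with an estimated correlation) and without day_0 replicate 2 (adjusted p = 0.0392, and adjusted p = 0.235 with an estimated correlation). Among them, APOE had 2.0 ± 0.874 (adjusted p = 0.291).

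**Figure D3:**
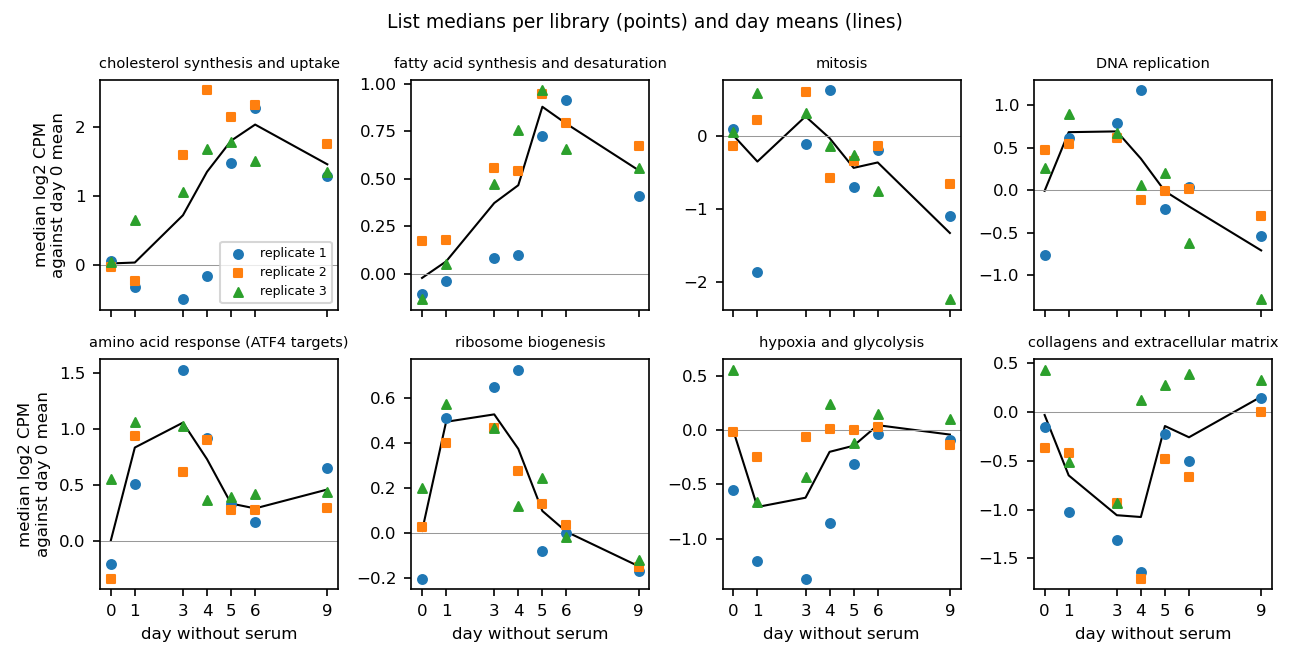
Median log2 CPM of 8 gene lists in each library, relative to the day 0 mean of each gene, against the day without serum (points, marker per replicate; lines, means of 3 libraries). The sterol list median of replicate 1 is -0.16 at day 4 and 1.47 at day 5, while replicate 2 is at 1.60 by day 3 and replicate 3 at 1.67 by day 4.

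Chaperones of the endoplasmic reticulum rose as a list at day 9, with 19 of 21 positive and a median of 0.46 (camera adjusted p = 3.71e-05, and adjusted p = 0.306 with an estimated correlation). Of these, 4 passed adjusted over the list alone and 1 over all genes. That gene, DNAJB9 (chromosome 7, 108210311 to 108215294), rose by 1.11 ± 0.248 (SE, n = 3 per day; edgeR adjusted p = 0.0487), and HERPUD1 and DNAJC3 had 1.08 ± 0.258 and 0.91 ± 0.22 (adjusted p = 0.0239 and 0.0302 with the replicate block). The amino acid response rose with 21 of 29 positive and a median of 0.35 (adjusted p = 8.74e-05, and adjusted p = 0.396 with an estimated correlation). Of these, 2 passed adjusted over the list alone and 1 over all genes. The cysteine tRNA ligase CARS (chromosome 11, 3022152 to 3078843) rose by 0.98 ± 0.207 (adjusted p = 0.0416), and NUPR1 and ASNS had 1.95 ± 0.556 and 1.37 ± 0.439. DNAJB9 and CARS were not called without any 1 of day_0 replicates 1 and 2 and day_9 replicates 1 and 2, nor with no filter, and DNAJB9 was also not called without day_0 replicate 3.

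Inflammatory cytokine and NF-kB genes fell as a list at day 9, with 5 of 22 positive and a median of -0.70 (camera adjusted p = 0.00658, and adjusted p = 0.299 with an estimated correlation; 0.0555 without day_9 replicate 2). Adjusted over the list alone 4 passed downward and 1 upward, and IL1B passed over all genes. The NF-kB inhibitor TNFAIP3 had a value of -1.91 ± 0.443 (SE, n = 3 per day; edgeR adjusted p = 0.0563, 0.0266 with the replicate block) and the cytokine IL33 -3.51 ± 0.859 (0.0652 and 0.0385). IL33 stood at 2.42 ± 1.51 against 27.7 ± 37.6 CPM, with a day 0 SD above the mean. Metallothioneins, whose members share near-identical sequence, were negative in 7 of 7, with a median of -1.45 (adjusted p = 0.00925, and adjusted p = 0.396 with an estimated correlation). MT2A, the pseudogene MT1L and MT1F had -1.45 ± 0.588, -1.72 ± 0.711 and -1.61 ± 0.89. MT1L had means under 1 CPM at both days, and MT1F stood at 0.874 ± 0.451 against 2.67 ± 2.8 CPM. NRF2 targets were positive in 7 of 22, with a median of -0.48 (adjusted p = 0.0204, and adjusted p = 0.541 with an estimated correlation). OSGIN1, HMOX1 and TKT had -2.22 ± 0.689, -1.63 ± 0.605 and -0.73 ± 0.273. HMOX1 stood at 15.3 ± 4.63 against 47.3 ± 52.6 CPM, with a day 0 SD above the mean. No member of the last 2 lists passed over all genes or adjusted over the list alone, and both lists were not called without day_0 replicate 3 (adjusted p = 0.416 and 0.482), without day_9 replicate 2 or with replicates 1 and 2 only. The other 22 lists were not called at day 9, with adjusted p from 0.063 (retinoid-responsive genes, median -0.20, with DHRS3 and RARRES1 called) to 0.98 (collagens and matrix). Pigment epithelium markers had 0.453.

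Among the other genes fixed by name, CDKN1A had a log2 fold change of -0.28 ± 0.274 at day 9 (SE, n = 3 per day), C3 -0.06 ± 0.39, EFEMP1 0.60 ± 0.523, TIMP3 -0.08 ± 0.276, SERPINF1 -0.16 ± 0.381 and VEGFA 0.55 ± 0.416, and none was called.

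**Figure D4:**
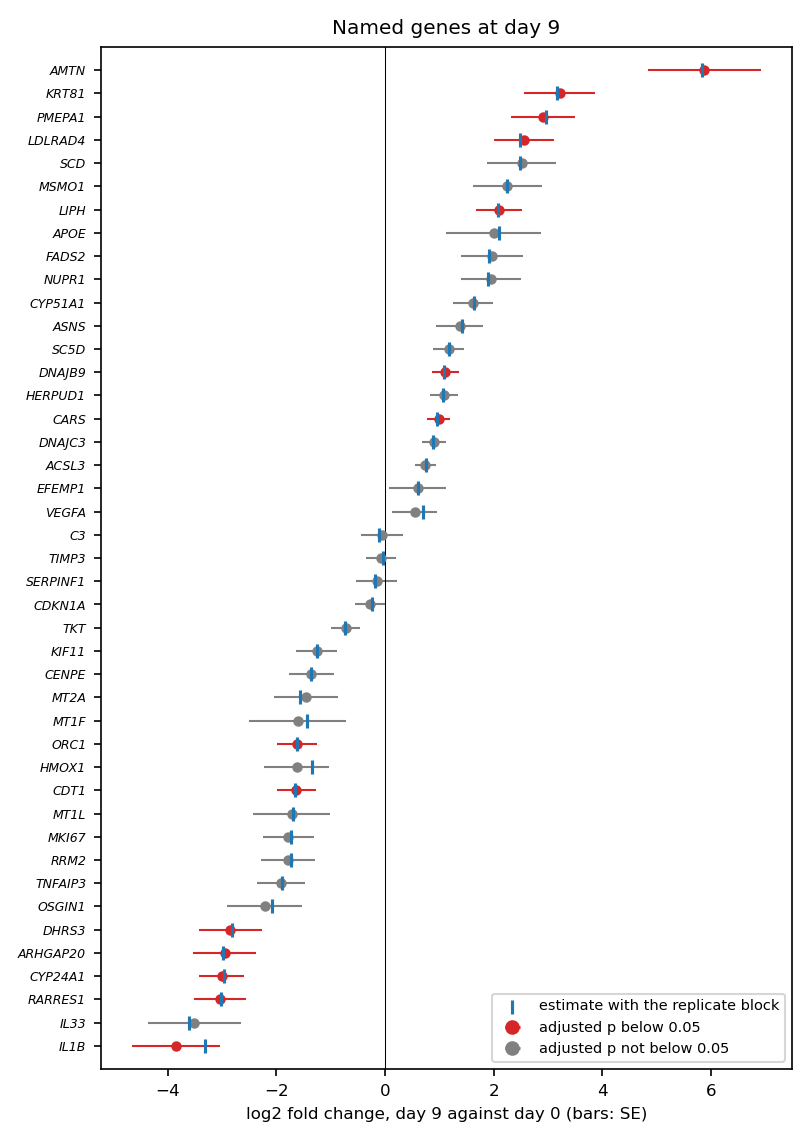
Log2 fold change of the named genes at day 9 against day 0 (points, bars are SE, n = 3 libraries per day; ticks, estimate with the replicate block), in red where the adjusted p was below 0.05. AMTN is highest at 5.87 and IL1B lowest at -3.85. IL1B stood at 10.3 ± 11.9 CPM (SD, n = 3) at day 0.

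Day 9 was compared with day 1 to separate late from early change. HR, a nuclear corepressor (chromosome 8, 21971932 to 21990897), rose by 2.96 ± 0.424 (SE, n = 3 per day; edgeR adjusted p = 0.0222; 8.44 ± 3.91 against 1.08 ± 0.41 CPM). RARRES1 fell, with -3.11 ± 0.481 (adjusted p = 0.0222), and TXK, a tyrosine kinase named after its values were seen, fell, with -2.86 ± 0.442 (adjusted p = 0.0222). These were the 3 calls, with 2054 genes at an unadjusted p under 0.05, 235 with the replicate block (145 up, 90 down) and 547 by DESeq2. Of the DNA replication list, 0 of 38 members were positive, with a median of -1.32, and 35 passed downward when adjusted over the list alone. CDT1, ORC1 and MCM5 had -2.03 ± 0.363, -1.90 ± 0.366 and -1.88 ± 0.365, with adjusted p of 0.0187, 0.0328 and 0.0328 with the replicate block. Of the sterol list, 24 of 24 were positive, with a median of 1.46 and 16 up when adjusted over the list alone. STARD4, SREBF2 and SC5D had 2.09 ± 0.469, 1.52 ± 0.357 and 1.18 ± 0.29, with 0.037, 0.0378 and 0.0469. No list was tested against other genes in this comparison. The count of 3 was 0 without day_1 replicate 3 and 1 without day_9 replicate 1 or 2, where RARRES1 was not called. RARRES1 was also not called without day_1 replicate 2. The count was 22 without day_1 replicate 1, 14 without day_9 replicate 3, 16 without day_0 replicate 1, and 111, 182 and 48 without day_4 replicates 1, 2 and 3.

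The other named members of the day 9 lists were not called against day 1. Of these, DNAJC3, DNAJB9, CXCL3, TNFAIP3 and IL8 were called with the replicate block, at adjusted p of 0.0468, 0.0413, 0.0328, 0.0481 and 0.0388. The mitosis genes MYBL2, MKI67 and BUB1B had log2 fold changes of -2.21 ± 0.624, -1.66 ± 0.472 and -1.75 ± 0.59 (SE, n = 3 per day), and day_1 replicate 1 had a list median of -1.86 against day 0. DNAJC3, DNAJB9 and HERPUD1 had 0.88 ± 0.22, 0.86 ± 0.247 and 0.72 ± 0.256. ATF5, PHGDH and ALDH1L2 had -1.72 ± 0.489, -0.73 ± 0.286 and 1.58 ± 0.63. ACSL3, SCD and FADS2 had 0.73 ± 0.192, 2.33 ± 0.638 and 1.74 ± 0.571. The chemokines CXCL3 and IL8 had -2.06 ± 0.388 and -1.51 ± 0.369, and TNFAIP3 -1.83 ± 0.442. MT2A and MT1E had -2.07 ± 0.599 and -2.17 ± 0.662, and MT1M stayed under 1 CPM. OSGIN1, AKR1B10 and SRXN1 had -2.12 ± 0.686, -2.12 ± 0.82 and -0.82 ± 0.35. AKR1B10 (0.207 against 0.91 CPM) and ALDH1L2 (0.668 against 0.221 CPM) also had means under 1 CPM at both days.

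Comparisons of neighbouring days asked when the changes set in, and edgeR called 0 genes in each of the 5. At an unadjusted p under 0.05, 750 genes would be expected by chance if p-values were evenly spread. Day 3 against 1 (239), day 6 against 5 (27) and day 9 against 6 (296) lay below that. With the replicate block these steps gave 729, 61 and 482. So 0 calls in these steps do not show that no gene changed. From day 1 to day 3, 239 genes had an unadjusted p under 0.05 and DESeq2 called 0. In that step 23 of 24 sterol genes were positive, with a median of 0.90, but in replicate 1 the list median went from -0.32 to -0.50. From day 3 to day 4, 1607 had an unadjusted p under 0.05, the replicate block gave 1 and DESeq2 0. Oxidative phosphorylation was positive in 33 of 35, with 16 up when adjusted over the list alone. From day 4 to day 5 it was positive in 2 of 35, with 22 down, both involving day_4 replicate 2. From day 4 to day 5, 2295 had an unadjusted p under 0.05 and DESeq2 called 0. From day 5 to day 6, 27 had an unadjusted p under 0.05 and DESeq2 called 1, and SCD moved by -0.25 ± 0.608 (SE, n = 3 per day). From day 6 to day 9, 296 had an unadjusted p under 0.05 and DESeq2 called 3. Mitosis was negative in 35 of 35, with a median of -0.92, and MKI67 had -1.37 ± 0.468. Without day_4 replicate 1 or 3, day 4 against day 3 gave 627 and 489 calls, without day_4 replicate 3 day 5 against day 4 gave 1521, and without day_6 replicate 3 day 6 against day 5 gave 1.

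Over all days together, edgeR called 29 genes, with 2438 at an unadjusted p under 0.05, 347 with the replicate block and 1471 by DESeq2. The count was 0 without replicate 1 of every day, 0 without replicate 2, and 194 without day_4 replicate 2. NID2 stood at 150 ± 50.5 CPM (SD, n = 3) at day 0 and 37.1 ± 5.84 at day 1, and CYP24A1 went from 1210 ± 341 CPM at day 0 to 150 ± 78.2 at day 9.

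**Figure D5:**
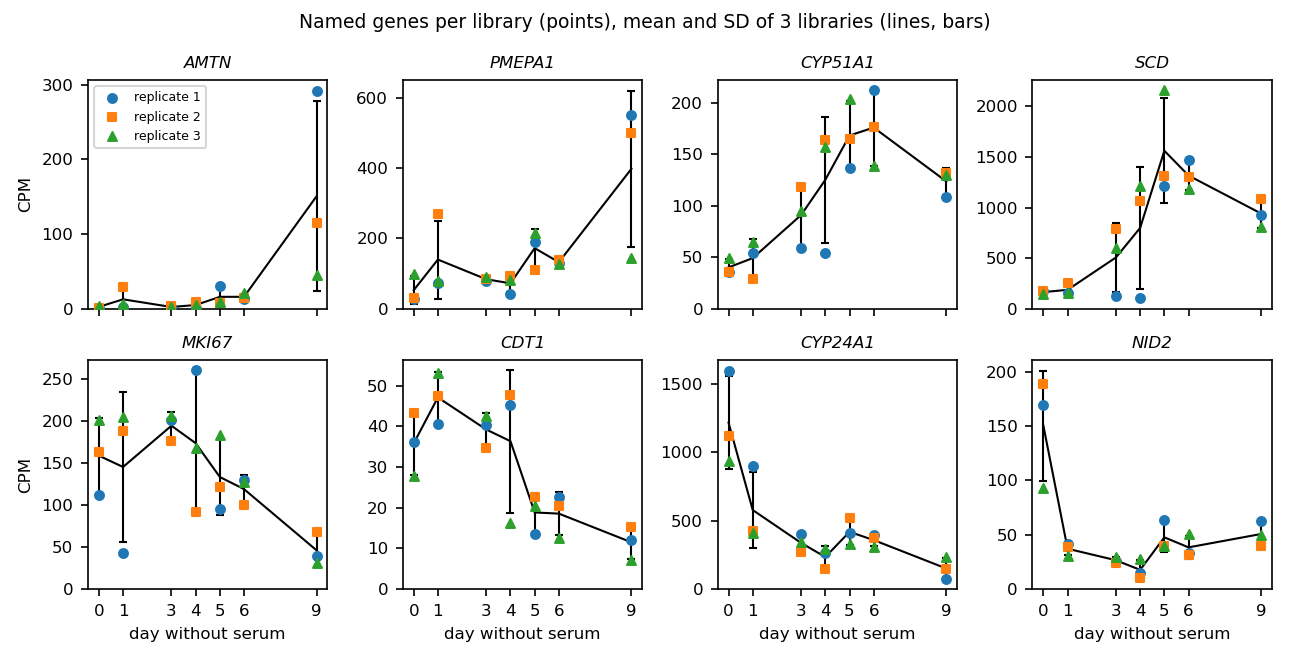
CPM of 8 named genes in each library against the day without serum (points, marker per replicate; lines and bars, mean and SD of 3 libraries). SCD in replicate 1 is at 110 CPM at day 4 and 1215 CPM at day 5, and CYP24A1 falls from a mean of 1210 CPM at day 0 to 150 CPM at day 9.

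The calls of days 1 and 9 against day 0 shared 0 genes by edgeR, where 0 genes were called at day 1 and 680 genes had an unadjusted p under 0.05 in the same direction at both days, against a simulated mean of 152. With the replicate block 11 genes were shared, 3 up (POMT2, NXF1 and TAF6L) and 8 down, NID2 and GPCPD1 among them. Independent lists would share 0.0733 up and 0.205 down, and 50 simulated draws with no effect and a shared day 0 gave a mean of 0.02 and at most 1. These draws hold no likeness between libraries with the same replicate number, so the 11 genes were set against a chance value that leaves this out. DESeq2 shared 98 genes, 37 up and 61 down. Without day_0 replicate 3 edgeR shared 178 and without day_4 replicate 2 it shared 34. The block fit without both day_3 replicate 3 and day_4 replicate 2, chosen after the data were seen, shared 473. No draws with a shared day 0 were simulated for DESeq2 or for these fits with libraries left out. Their counts were therefore not set against chance. The genes named here were chosen after their values were seen.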

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

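The alternatives without day_4 replicate 2, with replicates 1 and 2 only, and with the replicate block without day_3 replicate 3 and day_4 replicate 2 were chosen after the data were seen; the others were fixed before the data were examined. Single named genes were followed through both other scalings, both other filters, DESeq2, the replicate block and leaving out each library of the comparison. Of 22 named genes' calls, 1 (NID2 at day 4) was kept by all of these and 21 were lost by at least 1. In the fit of only days 0 and 4, outside this tally, NID2 was not called. Of 94 values not called, 52 were called by at least 1 of these alternatives and 9 changed sign. No called value reversed, and for 6 values an alternative gave none. With relative log expression factors and with the minimum of 1 CPM every count stayed within 1.5 times its value. In each case below the cause was not tested.

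With DESeq2 the counts of called genes were 280 (day 1 against 0), 529 (day 3), 1350 (day 4), 86 (day 5), 175 (day 6), 643 (day 9), 1 (day 6 against 5), 3 (day 9 against 6), 547 (day 9 against 1), 1471 (any day) and 98 (overlap of days 1 and 9). On simulated data 20.6% of DESeq2's calls were false, against 5.98% for edgeR. The simulated libraries lacked the replicate 3 difference and the outlying day_4 replicate 2, so these shares may not carry over to the real counts. With the replicate block they were 15, 367, 432, 9, 58 and 555 for days 1, 3, 4, 5, 6 and 9 against 0, 1 for day 4 against 3, 235 for day 9 against 1, 347 for any day and 11 for the overlap. With the block and without day_3 replicate 3 and day_4 replicate 2 they were 1376, 300, 1, 60, 400 and 1812 against day 0, 1410 for day 9 against 1, 1049 for any day and 473 for the overlap. With replicates 1 and 2 only they were 1 at day 1, 609 at day 4, 0 at day 5, 3 at day 6, 65 at day 9, 1 for day 6 against 5, 0 for day 9 against 1 and 1 for the overlap. Of these 65, 31 were among the 100 called with all libraries. At day 3 the count stayed 4, but only 1 gene was shared. Scaling by library size only gave 0 at day 3, 1 at day 4, 2 at day 5, 43 at day 9 and 10 for day 9 against 1. It moved the median of all genes from -0.01 to 0.105 at day 3, from -0.01 to 0.0944 at day 1 and from 0.04 to -0.112 for day 4 against 3. With no filter the counts were 63 at day 9, 8 for day 9 against 1 and 49 for any day. The test against a 1.5-fold change gave 0 at day 3, 1 at day 4, 0 at day 5, 2 at day 9 and 0 for day 9 against 1. Fits of only the 2 days compared gave 2 at day 3, 0 at day 4, 4 at day 5, 12 at day 6, 3 at day 9 and 6 for day 9 against 1. The 8 lists of day 1 and the 9 of day 9 each became 0 with an estimated correlation and 0 with fry. With replicates 1 and 2 only, the hypoxia, snoRNA host and SRF and YAP lists of day 1 and the metallothionein and NRF2 lists of day 9 were not called. The 12 lists of day 3 became 10 with replicates 1 and 2 only and stayed 12 without day_3 replicate 3, both chosen after the data were seen. The fit without day_3 replicate 3 kept day_0 replicate 3 and so does not test the part of that library. Without day_4 replicate 2 the lists of days 3, 4, 5 and 6 went from 12, 11, 10 and 9 to 11, 13, 11 and 8, and with the replicate block to 13, 11, 12 and 9.

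Leaving out 1 library, the counts against day 0 ran from 0 to 419 at day 1, 0 to 458 at day 3, 1 to 2223 at day 4, 0 to 50 at day 5, 0 to 181 at day 6 and 0 to 556 at day 9. The highest came without day_0 replicate 3 at days 1, 3, 5 and 6, without day_4 replicate 3 at day 4 and without day_4 replicate 2 at day 9. For neighbouring days they ran from 0 to 0 (day 3 against 1), 0 to 627 (day 4 against 3, highest without day_4 replicate 1), 0 to 1521 (day 5 against 4, highest without day_4 replicate 3), 0 to 1 (day 6 against 5) and 0 to 0 (day 9 against 6). Day 9 against 1 ran from 0 to 182 (highest without day_4 replicate 2), any day from 0 (without replicate 1 or 2 of every day) to 194 (without day_4 replicate 2) and the overlap from 0 to 178 (highest without day_0 replicate 3). Called lists ran from 3 (without day_0 replicate 3) to 12 (without day_1 replicate 3) at day 1 and from 6 (without day_9 replicate 2) to 15 (without day_0 replicate 1) at day 9. With 3 libraries per day, edgeR recovered 5 of 67 simulated 2-fold changes, so smaller changes were mostly out of reach, while 58 of 66 simulated 8-fold changes were called.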

Other observations

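The tests of replicate 3, of day_3 replicate 3 and of gene length in day_4 replicate 2, and the list tests for replicate 3, were chosen after the results were seen; the test of the chromosomes in day_4 replicate 2 and the repeats on other splits of the libraries were not. The time at which sterol genes turned on differed between the replicates. In replicate 1 the median of the cholesterol list against the day 0 mean was -0.32, -0.50 and -0.16 at days 1, 3 and 4 and 1.47 at day 5. Replicate 2 stood at -0.24 at day 1 and 1.60 at day 3, and replicate 3 at 0.65 at day 1 and 1.67 at day 4. Day_3 replicate 3, at 1.06, lacked the difference of the other replicate 3 libraries and does not show the timing in replicate 3. SCD in replicate 1 was at 110 CPM at day 4 and at 1215 CPM at day 5. With 1 library per day and replicate, the difference in timing was not tested.

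Replicate 3 also differed from replicates 1 and 2 in groups of genes. Of 32 tested collagen and matrix genes, 16 were higher and 1 was lower over all genes and adjusted over the list alone, with a median of 0.51 (camera adjusted p = 2.98e-07, and adjusted p = 0.889 with an estimated correlation). Matrix proteases were higher, with 7 members up and 1 down (adjusted p = 0.027, and adjusted p = 0.889 with an estimated correlation), as were hypoxia genes, with 6 up (adjusted p = 0.0238, and adjusted p = 0.934 with an estimated correlation). Oxidative phosphorylation (median -0.32, adjusted p = 0.00193, and adjusted p = 0.934 with an estimated correlation) and snoRNA hosts (median -0.42, adjusted p = 0.013, and adjusted p = 0.934 with an estimated correlation) were lower. KITLG, the ligand of the KIT receptor, was higher by a log2 fold change of 4.85 ± 0.535 and the imprinted gene NDN by 4.31 ± 0.38, while the cytokine IL18 had -3.67 ± 0.62 (edgeR, SE over 21 libraries). These SEs, counts and list p-values take libraries with the same number as independent, although replicate 3 is a single series. They also count day_3 replicate 3 with replicate 3.

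Replicate 3 stood apart at 6 of 7 days. Gene length, span, exon number or GC content would not explain it, since 148 of 150 genes with known properties stayed over 4-fold apart in at least 6 days after these were taken out. A small share of RNA from other cells would not lower genes far below their level, yet 18 genes were lower by over 8-fold in at least 6 days, UCA1 among them. A large share could lower genes this far, so this test does not exclude it. Another chromosome complement is a candidate explanation for part of it. All 17 windows of chromosome 11 were under -0.3, and the chromosome stood at 68.3% of the level of replicates 1 and 2. A segment of chromosome 15 (20584748 to 45011049) stood at 172% and the end of chromosome 5 (169288307 to 180699308, 2 windows) at 132%. Having 2 copies in place of 3 would give a log2 ratio of -0.585, and the reverse 0.585. The chromosome 15 segment had a median of 0.77, above that value. UCA1 on chromosome 19 (-7.56 ± 1.26) and KITLG on chromosome 12 (4.85 ± 0.535) lay far beyond both ratios. DNA was not measured, and the design names no group for replicate 3, so no biological explanation from the design was tested.

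Day_3 replicate 3 lacked this difference. A swap with a library of replicate 1 or 2 would leave a library with low chromosome 11 elsewhere, and the lowest level among those 14 libraries was 0.0313 (log2 against the mean of all). Cells of the kind held by replicates 1 and 2 may have been used, since the chromosome 11 median was 0.0276. RNA pooled from day_3 replicates 1 and 2 cannot be told apart from this: the best mixture, 37% of replicate 1 and 63% of replicate 2, left a chi-square of 19.6 per degree of freedom, too high for an exact pool but below the 27.99 of the closest pair of replicates. Day_3 replicate 3 lay between the other day 3 libraries in 68% of genes, against 33.3% by chance. The next highest share of this kind in the series was 55.4%, for day_6 replicate 1 among the day 6 libraries.

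Day_4 replicate 2 stood apart with high short transcripts, RMRP at 24.7 CPM against at most 1.83 CPM in the other libraries. Length, span, exon number and GC content accounted for part of the difference from replicate 1, but 837 genes stayed over 4-fold apart after these were taken out, against at most 224 at another day, which argues against them as the whole cause. Cells with the chromosome 11 level of replicate 3 would have shown a low chromosome 11, and the corrected chromosome 11 median was 0.114. The other autosomes, outside this test, ran from -0.0934 (chromosome 4) to 0.106 (chromosome 10). Medians of whole chromosomes cannot show a change in part of one, so other complements were not excluded. RNA quality remains open and was not tested, and the design names no group that would set this library apart.

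The real division of each 6 libraries was compared with the other divisions of the same 6. For 3 libraries against 3 there are 10 divisions, too few for a share under 0.05. At day 9 the real division gave 100 genes and the highest other 0, at day 3 it gave 4 and 0, and at day 5 it gave 1 and 0; in each of these 3 cases 1 of 10 gave as many. At day 4 the real division gave 6 and the highest other 773 (2 of 10 as many), with day_0 replicates 1 and 2 grouped with day_4 replicate 2, against both replicate 3 libraries and day_4 replicate 1. That division parts the replicate 3 libraries from day_4 replicate 2, which stand apart as described above. So does the division with day_0 replicate 1 and day_4 replicates 1 and 2 together, and that with day_0 replicate 2 in place of day_0 replicate 1. Both gave 0 genes, so this parting alone does not account for the 773, and the cause was not tested. At day 1 it gave 0 and 25 (10 of 10 as many), where divisions parting 3 pairs gave 0; at day 6 it gave 0 and 1 (10 of 10), and for day 9 against day 1 it gave 3 and 15 (2 of 10), where those parting 3 pairs gave 0. For day 3 against 1, day 4 against 3, day 5 against 4, day 6 against 5 and day 9 against 6 the real value and the highest other were both 0 (10 of 10 each). At day 1 the real division called 8 lists against a highest other of 14 (6 of 10 as many, 12 where 3 pairs are parted). At day 9 it called 9 against 13 (4 of 10 as many, 13 where 3 pairs are parted). The number of called lists thus did not set the real division apart. Over all days, 7 of 100 divisions gave at least the real 29 genes, with a highest other of 348, so chance is not excluded. These divisions were drawn without regard to the replicate number, so they leave out the likeness of libraries with the same number.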
